A study of Drosophila melanogaster with 4 samples.

How the data were processed

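Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole third-instar larvae of the wild-type Oregon-R strain of Drosophila melanogaster, with an antibody against HP1b. Per the labels' protocols, tissue was homogenised, crosslinked with formaldehyde and broken open by SDS and ultrasound, and the soluble chromatin was incubated with the antibody, washed and reverse crosslinked. The samples were 2 HP1b ChIP libraries and 2 Input libraries, grouped by their titles. Cluster files of the 2 ChIP libraries and 1 file of the whole series were analysed here, and the Input libraries had no file of their own among them. Nothing in the labels says whether the 2 ChIP libraries came from separate larval collections, so the spread between them may be technical.

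Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The peak caller, its threshold and its filters are not given in the sources used here. Coordinates are on FlyBase release 5 of the genome, per the file headers, which also give the length of each sequence. Each deposited row is 1 cluster with its start, end and 1 log2 score that the authors assigned. What the log2 score divides by what, and its scaling, are not stated in the sources used here. That its base is 2 was inferred from the values. Among scores shared exactly by 3 or more clusters, 38 pairs in replicate 1, 56 in replicate 2 and 138 in the combined set differed by the base-2 logarithm of a ratio of small whole numbers, to within 1e-06. With natural logarithms these counts were 0, 0 and 1, and with base 10 they were 0, 0 and 0. The score was used to describe and rank clusters within a list, and to compare chromosome classes in the difference between replicates, where a constant scaling of either library cancels.

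Clusters were called per library in the 2 ChIP files. The file of the whole series is named as a replicate set and is described here as the authors' combined set. It is not independent of the replicates, and its values carry no error. Rows that the authors marked as significant depletion (1 in replicate 2 and 2 in the combined set) were left out of every count of clusters. Clusters within a file did not overlap each other. The files hold no read counts, so sequencing depth is unknown and no limit from depth could be set.

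Sequences were classed by name as the long arms (2L, 2R, 3L, 3R and X), chromosome 4, the Het scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, which hold mapped heterochromatin) and U (unplaced sequence). The covered share is the percentage of a sequence's bases that lie in a cluster. It was computed per replicate and is given as mean ± SD with n = 2. With files for 1 group, groups were not compared, and an exact two-sided sign test over 2 libraries cannot go below p = 0.5. Overlap counted 1 bp as touching. Its chance level came from 1000 circular shifts of one list within each sequence, which keep cluster widths and spacing, and the one-sided p-value is the share with at least the observed overlap among the shifts and the observed arrangement together. Benjamini-Hochberg adjustment was over 15 such comparisons. Intervals on shares of clusters are 95% Wilson intervals and cover counting error only. Neighbouring clusters are not independent, and these tests describe the 2 libraries.

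The proximal (centromere-facing) end of an arm was its last 2 Mb for 2L, 3L and X and its first 2 Mb for 2R and 3R. As a description of how unusual an end was, it was set against all circular stretches of the same length on its arm in 1-kb steps. Neighbouring stretches share nearly all their bases and an arm holds few separate ones, so the shares are not p-values. This comparison was added after the data were seen. Clusters were matched between replicates by largest overlap, each used once.

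The regions to name were chosen by a rule set before the data were examined. It took the 10 combined clusters with the highest score and the 10 widest combined clusters on the long arms, all touched by a cluster of both replicates, plus the widest combined cluster of each other sequence. Gene features and gene lists had also been planned on the condition that the annotation matched the coordinates. The gene table at hand is of release 6 and the clusters are of release 5, so no gene was assigned to any cluster and those comparisons and their alternatives were not run.

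Alternatives fixed before the data were examined were a minimum width of 1000 bp, merging of clusters under 1000 bp apart, the higher-scoring 50% of each list, stricter overlap (50% covered, or reciprocal 50%), cluster number in place of bases, proximal ends of 1 and 4 Mb, the long arms alone, each replicate alone and the combined set. Leaving the proximal 2 Mb out of the long arms, and leaving out combined clusters narrower than 1301 bp, were added afterwards. The overlap test was checked on simulated data made from the 5191 replicate 1 clusters. Shares of 0%, 20.0% and 50.0% of clusters were planted as exact copies in a second list, and the rest were placed at random. Over 5 runs each, with fewer than the 1000 shifts used for the replicate lists, the test called 0, 5 and 5 of the runs. The planted share was recovered at 0.021%, 20.3% and 49.8% on average. That recovery used a chance level from the clusters known to be unplanted, so its closeness is largely built in. Random placement does not keep the spacing of real clusters, and 5 runs are too few to give a rate of false calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.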

Results

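HP1b binding was mapped in whole third-instar larvae of wild-type Drosophila melanogaster. HP1b belongs to the heterochromatin protein 1 family, whose founding member, HP1a, is a chromodomain protein that binds methylated histone H3 in the heterochromatin around centromeres and on chromosome 4. The data were the enriched clusters of 2 ChIP libraries and the authors' combined set. The design asks where in the genome HP1b was enriched and how far the 2 libraries agreed. Replicate 1 held 5191 clusters over 12995342 bp and replicate 2 held 6337 clusters over 16828856 bp, a mean of 5764 ± 810.3 clusters (SD, n = 2) and 14.9 ± 2.71 Mb (SD, n = 2). The combined set held 8426 clusters over 21.3 Mb. Clusters were of similar size in both libraries, with a median width of 2174 bp in replicate 1 and 2272 bp in replicate 2. The widest cluster of replicate 1 measured 19890 bp and that of replicate 2 measured 17152 bp. Sequencing depth is unknown, as the files hold clusters and not reads.

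HP1b clusters were densest on chromosome 4, the small and largely heterochromatic autosome. They covered 32.9% ± 3.28 of chromosome 4 (SD, n = 2), against 11.6% ± 2.40 of the long arms (SD, n = 2). The covered share of chromosome 4 was 3.56 times that of the long arms in replicate 1 and 2.30 times in replicate 2. In the authors' combined set, clusters covered 47.8% of chromosome 4 and 15.8% of the long arms. Chromosome 4 still held a small part of all bound sequence. It carried 3.66% of cluster bases in replicate 1 and 2.45% in replicate 2, while the long arms carried 90.6% and 93.9%.

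**Figure D1:**
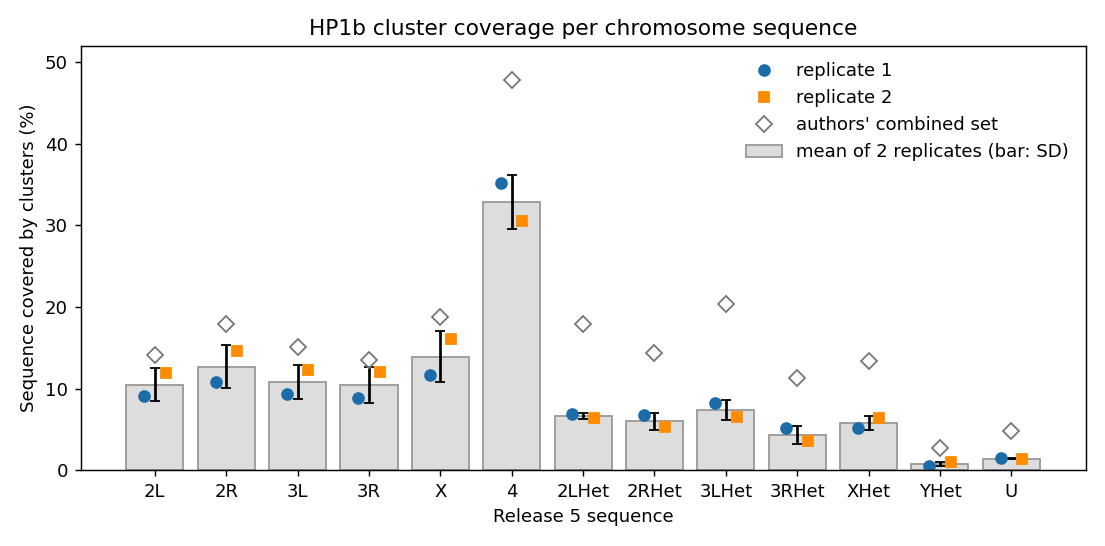
Percentage of each release 5 sequence covered by HP1b clusters. Grey bars are the mean of 2 replicates with the SD, circles and squares are the replicates, and diamonds are the authors' combined set. Chromosome 4 stood at 35.2% in replicate 1 and 30.6% in replicate 2, above every other sequence.

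Both replicates had wider clusters on chromosome 4 than on the long arms, while the scores there were not higher. The median cluster width on chromosome 4 was 3093 bp in replicate 1 and 2524 bp in replicate 2, against 2189 bp and 2280 bp on the long arms. In the combined set, which holds narrower clusters, the medians were 2145 bp on chromosome 4 and 2185 bp on the long arms. Chromosome 4 held 12 of the 22 clusters of at least 10 kb in replicate 1 and 7 of 29 in replicate 2. Per Mb this came to 8.88 and 5.18 such clusters, against 0.0518 and 0.124 on the autosomal long arms. In the combined set chromosome 4 held 19 of 64 such clusters, or 14.1 per Mb against 0.290 on the autosomal long arms. Counted as clusters per Mb in place of bases, chromosome 4 exceeded the long arms by a mean factor of 1.71. The median score of chromosome 4 clusters lay at percentile 48.4 of the replicate 1 list and at percentile 34.2 of the replicate 2 list. The widest cluster of the combined set lay on chromosome 4 at 195124 to 217454 (22.3 kb), and clusters of replicate 1 covered 98.3% of it and those of replicate 2 covered 82.6%.

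**Figure D2:**
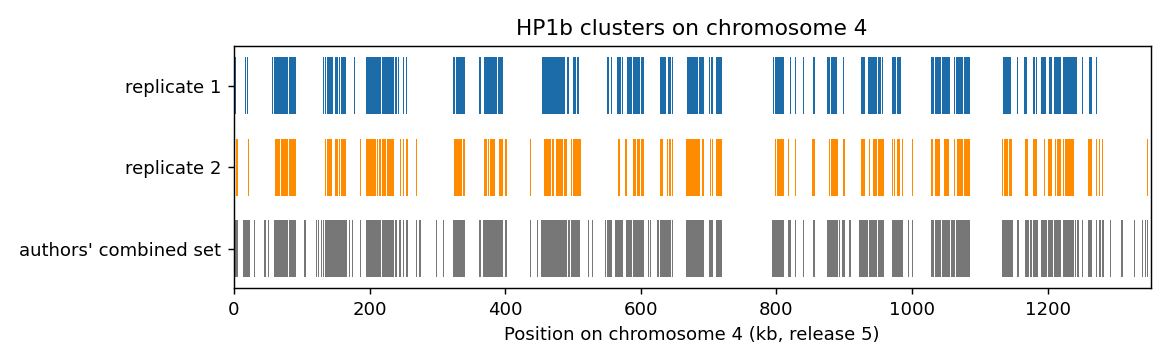
HP1b clusters along chromosome 4 (position in kb, release 5) in replicate 1, replicate 2 and the authors' combined set, each bar being 1 cluster drawn to scale. Clusters lay in blocks shared by both replicates, with a stretch of 74.1 kb between 719683 and 793821 free of clusters in all 3 lists.

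Among the long arms, X had the largest covered share in both libraries. Clusters covered 11.7% of X in replicate 1 and 16.1% in replicate 2, against 9.47% and 12.6% of the autosomal long arms. The ratio of X to the autosomal arms was 1.26 ± 0.0313 (SD, n = 2). The autosomal arms ranged from 8.87% (3R) to 10.8% (2R) in replicate 1 and from 11.9% (2L) to 14.6% (2R) in replicate 2. X clusters also scored higher within each list, with a median at percentile 57.3 in replicate 1 and 56.6 in replicate 2, against 48.2 and 48.8 for the autosomal arms. Both libraries had a ratio above 1, and an exact two-sided sign test over 2 libraries cannot go below p = 0.5.

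The Het scaffolds were covered less than the long arms in both replicates. Clusters covered 6.48% of them in replicate 1 and 5.05% in replicate 2, which is 0.656 and 0.381 times the share of the long arms. The scaffolds of chromosome 3 bracketed the larger ones, with 8.30% and 6.56% of 3LHet covered and 5.13% and 3.53% of 3RHet. On YHet, replicate 1 had 1 cluster and replicate 2 had 2. Unplaced sequence (U) was covered to 1.48% and 1.36%. No list had a cluster on Uextra. In the combined set the Het scaffolds reached 14.9%, 0.943 times the long arms, so the difference in bases seen in the replicates was much smaller there. By number the combined set went the other way, with 66.5 clusters per Mb on the Het scaffolds and 62.0 on the long arms. Repeats limit how many reads can be placed on Het and U sequence, and the files do not say which bases were mappable.

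Coverage near the centromeres differed between arms. The proximal 2 Mb of 2R were covered to 20.4% in replicate 1 and 18.0% in replicate 2, against 9.81% and 14.2% of the rest of the arm, a ratio of 2.07 and 1.27. Of all 2-Mb stretches of 2R, which overlap heavily, 0.828% and 1.56% were covered at least as much. The shares were 4.41% and 10.7% for the proximal 1 Mb, and 0.184% and 2.20% for the proximal 4 Mb. The proximal 2 Mb of X went the other way, with 5.71% and 7.46% covered against 12.3% and 17.0% of the rest, a ratio of 0.466 and 0.439. Only 0.290% and 0.272% of 2-Mb stretches of X were covered as little. Over the proximal 4 Mb the mean ratio of X moved from 0.453 to 0.684, and 8.24% and 8.15% of 4-Mb stretches were covered as little. On 2L the ratio was 1.55 and 1.16, and on 3R it was 1.27 in both, with a mean of 1.03 over the proximal 4 Mb. On 3L the replicates did not share a direction over the proximal 2 Mb, at 1.02 in replicate 1 and 0.614 in replicate 2. Both were below 1 over the proximal 1 Mb (0.970 and 0.489) and the proximal 4 Mb (0.883 and 0.738). The 2-Mb stretches covered at least as much were 4.82% and 28.5% on 2L, 7.76% and 9.65% on 3R, and 49.9% and 98.3% on 3L. Over the 5 arms together the ratio was 1.24 in replicate 1 and 0.925 in replicate 2, a mean of 1.08 ± 0.221 (SD, n = 2), which does not exceed the spread between replicates.

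**Figure D3:**
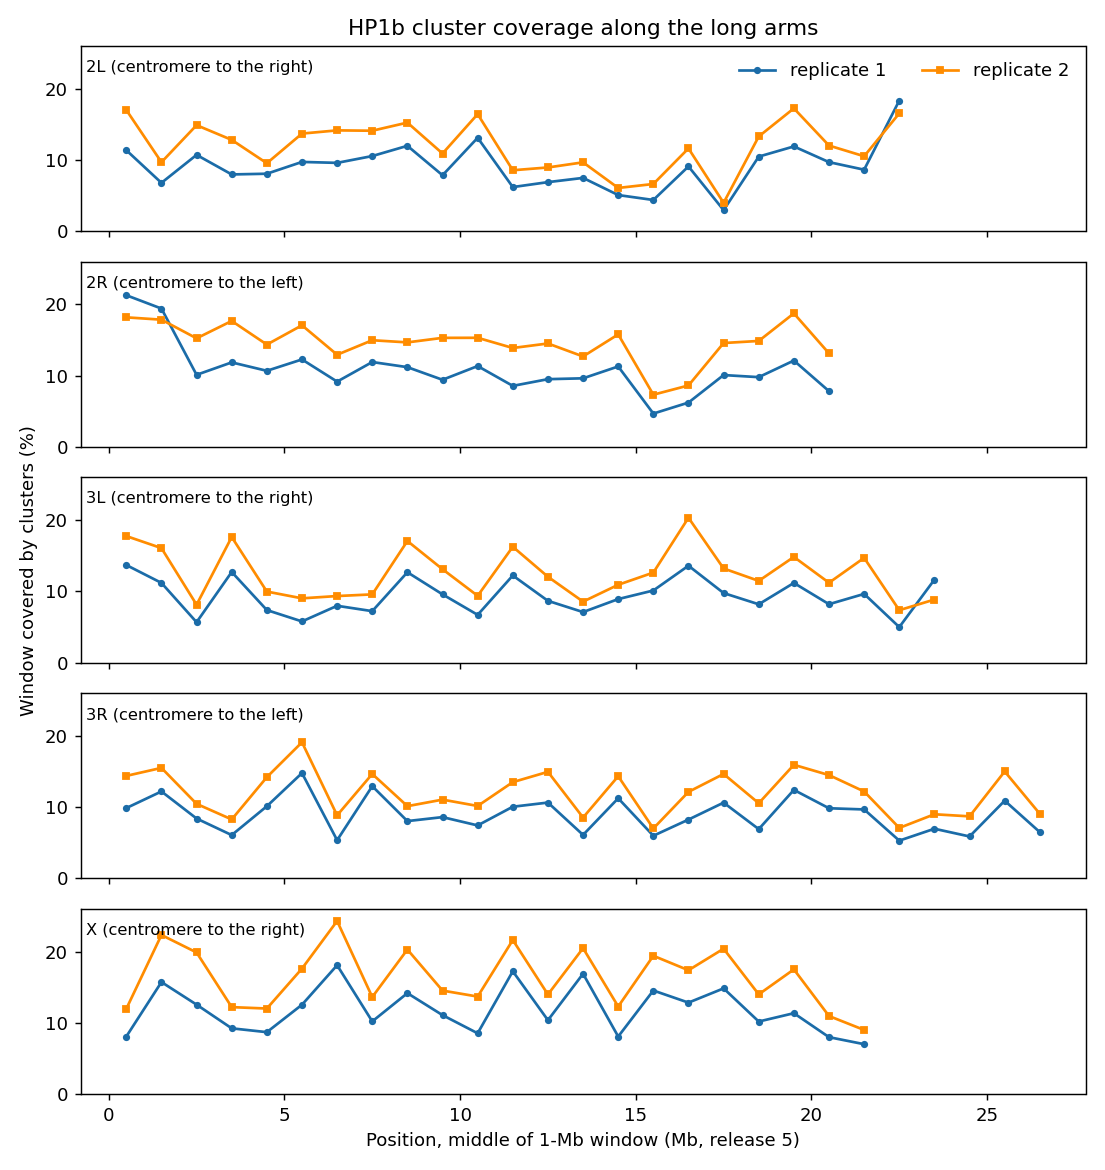
Percentage of each full 1-Mb window covered by HP1b clusters along 2L, 2R, 3L, 3R and X (middle of the window in Mb, release 5), with 1 line per replicate. In replicate 1 the highest windows of 2L (18.3%) and 2R (21.3%) were the centromere-proximal ones, while the last full window of X was its lowest in both replicates (7.03% and 9.02%).

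Several other windows were the extremes of their arm in both libraries. The densest window of X was 6000001 to 7000000, with 18.1% covered in replicate 1 and 24.3% in replicate 2. The densest window of 3R was 5000001 to 6000000, with 14.8% and 19.1%. The sparsest window of 2L was 17000001 to 18000000, with 2.95% and 3.98%, and that of 2R was 15000001 to 16000000, with 4.68% and 7.33%. The sparsest full window of 3L, at 22000001 to 23000000, lay partly within the proximal 2 Mb and had 5.00% and 7.37%. The densest window of 2L, 2R and 3L and the sparsest of 3R differed between the libraries.

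The 10 highest-scoring combined clusters that both replicates touched all lay on the long arms, 3 of them on X and 4 on 2R. The condition of touch bears on this, as it kept 56.1% of combined clusters on the long arms, 39.3% on chromosome 4, 15.9% on the Het scaffolds and 8.19% on U. Without it the highest combined score was 3.58, and 25.6% of U clusters were in the top 10% of combined scores, against 9.77% on the autosomal long arms. The highest of the 10 was on X at 19412928 to 19418710, with a log2 score of 3.19 in the combined set, 2.92 in replicate 1 and 3.72 in replicate 2. The next were X 5222218 to 5225196 (combined score 3.17) and X 1772462 to 1775758 (combined score 3.15). On 2R they were the clusters at 11014252 to 11018270, 2548474 to 2552184, 4996044 to 4999566 and 8766208 to 8768888, with combined scores from 3.02 to 3.11. The remaining 3 were at 18687732 to 18690758 on 2L (3.05), at 11054040 to 11056632 on 3R (3.03) and at 4623164 to 4630530 on 3L (3.03). These clusters were 2.59 to 7.37 kb wide, all above the combined median width of 2129 bp.

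The widest clusters of the long arms were a different set of regions. Of the 10 widest that both replicates touched, 5 lay within the proximal 2 Mb of 2R and 2 within the proximal 2 Mb of 2L. The widest was at 1137400 to 1154894 on 2R (17.5 kb), covered to 87.3% by replicate 1 and to 98.0% by replicate 2. It was followed on 2R by 1216882 to 1232902 (16.0 kb) and 1008782 to 1024024 (15.2 kb). Of the 3 outside the proximal ends, 1 lay on 2R at 17587302 to 17602536 (15.2 kb), 1 on 3R at 23741212 to 23756046 (14.8 kb) and 1 on X at 8782160 to 8796580 (14.4 kb). The combined scores of all 10 ranged from 0.851 to 1.78, above the combined median score of 0.502. The widest clusters of the heterochromatic scaffolds were 15.9 kb on 3LHet (2186786 to 2202718), 15.6 kb on 2RHet (1617120 to 1632746), 11.7 kb on 2LHet (163992 to 175738) and 9.43 kb on 3RHet (1804744 to 1814168). Those of XHet and YHet measured 2.94 kb and 2.02 kb, and the widest on U measured 14.2 kb. Both replicates had a cluster in each of these.

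The 2 libraries placed most clusters at the same positions. Of replicate 1 clusters, 87.8% (95% Wilson interval 86.9 to 88.7) were touched by a replicate 2 cluster, against 23.4% on average and at most 27.3% in 1000 circular shifts. Of replicate 2 clusters, 70.7% (69.6 to 71.8) were touched by replicate 1, against 19.3% on average and at most 22.3% by shifting. By this permutation of positions both had p = 0.001, the smallest that 1000 shifts can give (adjusted p = 0.00115). The shifts run over the whole length of each sequence, so the chance level takes no account of which positions both libraries could map. The lists shared 61.4% of the bases that either covered, against 6.28% by shifting. Over the 4395 clusters matched between the libraries, scores correlated with a Spearman rho of 0.841 across clusters, which are not independent replicates. Wider clusters scored higher over all sequences, with a rho of 0.717 in replicate 1 and 0.744 in replicate 2, but on the Het scaffolds rho was 0.338 and 0.507, and in the combined set it was 0.585 over all sequences and -0.0374 on the Het scaffolds.

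**Figure D4:**
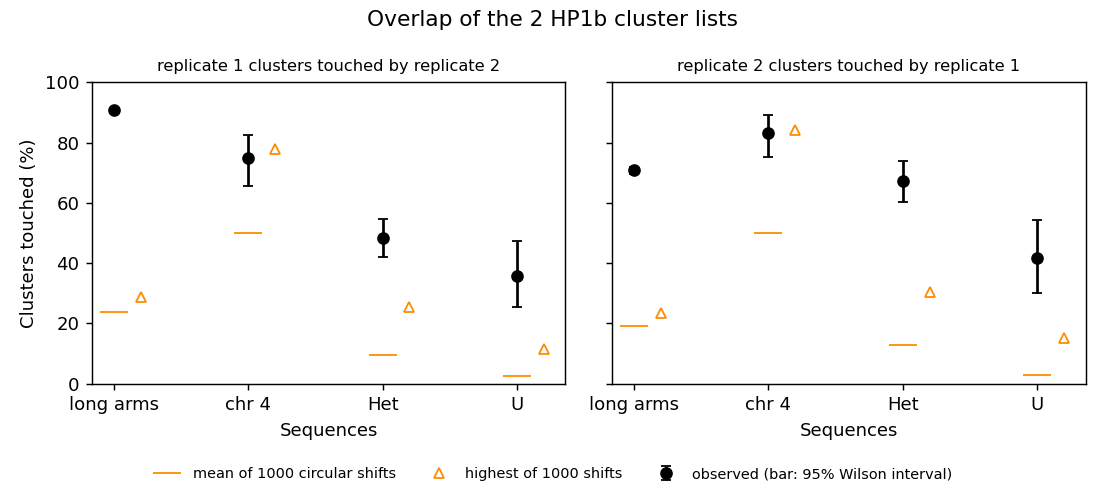
Percentage of clusters of one replicate touched by a cluster of the other, by sequence class. Black points are observed shares with 95% Wilson intervals, orange dashes the mean and triangles the highest of 1000 circular shifts. Among replicate 1 clusters the share was highest on the long arms (90.8%), among replicate 2 clusters on chromosome 4 (83.3%), and in both it was lowest on U (35.7% and 41.7%).

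Agreement differed by class. On the long arms 90.8% of replicate 1 clusters were touched by replicate 2, on chromosome 4 it was 75 of 100 clusters, on the Het scaffolds 48.3% and on U 35.7%. In the other direction the shares were 70.9%, 83.3%, 67.4% and 41.7%. On chromosome 4 dense coverage made chance overlap high, at 50.1% and 50.0% by shifting, and the observed shares had adjusted p-values of 0.004 and 0.00321 by the shift test. Replicate 2 covered more of each long arm than replicate 1, a ratio of 1.34 over the 5 arms, but less of chromosome 4 (0.868) and of the Het scaffolds together (0.780). By number, replicate 2 had 108 clusters on chromosome 4 against 100 in replicate 1. The small scaffolds XHet (ratio 1.24) and YHet (1.70), with 6 clusters or fewer in either library, went with the long arms.

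The authors' combined set held nearly all replicate clusters and many that neither replicate had. It touched 98.8% of replicate 1 clusters and 98.3% of replicate 2 clusters. Of its 8426 clusters, 51.3% (95% Wilson interval 50.2 to 52.4) were touched by both replicates, 6.52% by replicate 1 alone, 20.6% by replicate 2 alone and 21.6% by neither. The part touched by neither was 16.6% on the long arms, 35.3% on chromosome 4, 57.7% on the Het scaffolds and 67.3% on U. Those clusters had a median width of 1217 bp, against 2655 bp for clusters touched by both. The narrowest cluster measured 1301 bp in either replicate but 1001 bp in the combined set, and 1072 of the 1821 clusters touched by neither were narrower than 1301 bp. Among combined clusters of at least 1301 bp, 10.5% were touched by neither, and the share was 7.65% on the long arms, 19.6% on chromosome 4, 40.5% on the Het scaffolds and 45.3% on U.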

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

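Values were taken to stay where a tested overlap kept its direction and its side of the threshold, a count stayed within 1.5 times, a ratio within 1 SD between replicates, a share within its 95% Wilson interval and a correlation within 0.05. Of the 47 alternatives tried on the results that answer a comparison, 11 had no room to move beyond their tolerance. For 8 of them, 1 of 2 replicates always lies within 1 SD of their mean, so only a reversal of direction could show, and 1 reversed. For the other 3, the minimum width of 1000 bp removed no cluster. Of the other 36, 24 stayed, 12 moved and none reversed. Overlap between the replicates exceeded its shifted level under all 4 alternatives in both directions, with 79.7% of replicate 1 clusters and 65.3% of replicate 2 clusters overlapping reciprocally by 50%. Keeping the higher-scoring 50% of each list left 2596, 3169 and 4213 clusters in replicate 1, replicate 2 and the combined set by construction. The share of combined clusters touched by both replicates was 49.0% when 50% had to be covered, 53.5% in the higher-scoring 50% of each list, and 60.5% among combined clusters of at least 1301 bp, which was chosen after seeing the data. The ratio of chromosome 4 to the long arms was 1.71 by cluster number, and 2.30 and 3.56 with one replicate each. The ratio of the Het scaffolds to the long arms was 0.381 and 0.656 with one replicate each and 0.943 in the combined set, and the cause was not tested. The ratio of X to the autosomal arms was 1.18 by cluster number, 1.46 in the higher-scoring 50% of each list and 1.35 without the proximal 2 Mb of each arm, an alternative chosen after seeing the data. The proximal ratio over the 5 arms was 1.40 in the combined set and ranged from 0.925 without replicate 1 to 1.24 without replicate 2, so replicate 1 decides its direction; the cause was not tested. For 3L alone it was 0.815 over both replicates, ranged from 0.614 without replicate 1 to 1.02 without replicate 2, and was 1.39 in the combined set; the cause was not tested. For single arms, of the 20 alternatives with room to move 9 stayed, 10 moved and 1 reversed, and of the 10 with one replicate left out 1 reversed, both reversals on 3L. No paired analysis was possible because the Input libraries that share replicate numbers with the ChIP libraries had no file among those analysed. Planned comparisons of gene features and gene lists were not run, for want of an annotation on release 5. Read depth is unknown, so how far it limits calls on repeat-rich sequence cannot be stated.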

Other observations

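Of the tests below, the one of a uniform difference between replicates and the comparison of 1-Mb windows of X were chosen after their results had been seen. Clusters on chromosome 4 were unevenly spread. Of its 27 full 50-kb windows, 7 in replicate 1 and 5 in replicate 2 were covered to at least 50%, with a maximum of 80.1% and 65.4% in the window from 200001 to 250000. The window from 400001 to 450000 had 0% in replicate 1 and 7.92% in replicate 2, and that from 750001 to 800000 had 7.99% and 3.06%. On the long arms, the longest stretches without a cluster in any of the 3 lists were 335 kb on 3R (23815693 to 24150967), 314 kb on 2L (16928005 to 17242497), 251 kb on 3L (13660787 to 13912021), 232 kb on X (14142718 to 14374811) and 203 kb on 2R (16215973 to 16418501). Whether assembly gaps or unmappable sequence lie in them was not examined. The authors also marked depleted clusters, 1 on 3L in both replicate 2 (11480139 to 11481767) and the combined set (11480160 to 11481814) and 1 on 2L in the combined set (13215106 to 13216922), with scores from -0.0436 to -0.0167.

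Replicate 2 covered more bases of each long arm than replicate 1 but fewer of chromosome 4 and of the Het scaffolds together, although its number of clusters on chromosome 4 was higher (108 against 100). The arms were not uniform in this. The proximal 2 Mb of 2R (20.4% in replicate 1 and 18.0% in replicate 2) and of 3L (9.51% and 7.82%) were also covered less in replicate 2. Those of 3R and X were covered more. Those of 2L were nearly unchanged (13.4% and 13.6%), while the rest of 2L rose from 8.66% to 11.7%. The proximal 1 Mb of 2L was covered less in replicate 2 (18.3% and 16.9%). Relative to the rest of the arm, the proximal 2 Mb were lower in replicate 2 on 2L (ratio 1.55 and 1.16), 2R (2.07 and 1.27) and 3L (1.02 and 0.614). The ratio changed little on X (0.466 and 0.439) and was 1.27 in both replicates on 3R. Over clusters matched between replicates, the median log2 score difference (replicate 2 minus 1) was 0.312 on the long arms, -0.0289 on chromosome 4 and 0.0418 on the Het scaffolds. Chromosome 4 and Het together (177 clusters) differed from the long arms by -0.289, with a two-sided permutation p of 0.0001, the smallest that 10000 permutations can give. Against long-arm clusters of like replicate 1 score, the difference was -0.227 (bootstrap 95% interval -0.250 to -0.209). The interval is over clusters, which are not independent, and compares 1 library with 1. It argues against a constant score difference between the libraries. How a difference in depth would act on the scores is unknown, as their scaling is not stated. It argues less firmly against a stretch of all scores in replicate 2, as clusters were matched on the replicate 1 score alone. Matched scores do not test a difference in calling threshold. Clusters were not matched on width. In replicate 1 the matched clusters had a median width of 4385 bp on chromosome 4, 2415 bp on Het and 2243 bp on the long arms. A difference that goes with width was therefore not separated from one of class. The score difference of -0.227 goes with a lower enrichment of chromosome 4 and Het relative to the arms in replicate 2. Whether this comes from the larvae, the precipitation or the Input library used stays open, and no biological explanation was tested.

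X had a larger covered share than the autosomal arms in both replicates. In the higher-scoring 50% of each list X over autosomal coverage was 1.45 in replicate 1 and 1.47 in replicate 2, so the excess was not confined to low-scoring calls. X clusters score higher within each list, so a high ratio in this part was to be foreseen. A general upward shift of X scores would give the same result and carry more calls over the threshold, so the comparison cannot exclude it. Nor was the excess confined to a few dense windows: the median 1-Mb window of X (22 windows) exceeded that of the autosomal arms (95 windows) by 1.61 percentage points in replicate 1 and 2.85 in replicate 2. Two-sided permutation p-values over windows were 0.04 and 0.0187. Windows are not independent, and the autosomal arms differ among themselves, so these p-values are descriptive. The highest autosomal median was that of 2R, at 10.1% and 14.9%, against 11.2% and 16.0% on X. The sex of the larvae is not in the labels, and effects of X copy number on reads, Input or scaling remain open because no read counts were analysed.

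Many of the highest scores of the combined set are exact repeats of one another. Of its 100 highest-scoring clusters, 37 had a score shared by at least 3 clusters, against 6.02% of all 8426 clusters, and on U the share was 33.1%. Ratios of small whole numbers produce such ties, so few reads are a candidate explanation. Clusters with a shared score were touched by a replicate cluster less often than others, by -30.8 percentage points on the long arms and -24.5 on Het and U (permutation p = 0.0001, the smallest possible here), but they were also narrower (median 1409 against 2217 bp and 1056 against 1672 bp). Against other clusters of like width the differences were -0.353 and 1.06 percentage points (permutation p = 0.863 and 0.751), so the lower share goes with width. If few reads themselves made these clusters narrow, matching on width would remove their effect. The comparison is therefore evidence neither for nor against few reads, which stay open. Same-score pairs also had the same width more often than with shuffled widths (125 pairs against 27.0 on average, permutation p = 0.0001), as copies of one repeat would. With widths shuffled only among clusters of like score and class the average rose to 71.6 (permutation p = 0.0001), so part of the excess goes with score or class in general and not with the exact score. All 125 pairs were of clusters narrower than 1301 bp: among wider clusters there were 0 such pairs against 0.471 on average, too few to decide, so copies of one repeat and a finer pile-up of near-minimal widths both stay open.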
